A study of Mus musculus with 2 samples.

How the data were processed

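Lung leukocytes of CXCL2-GFP reporter mice were measured by droplet single-cell RNA sequencing (10x Genomics). The mice were heterozygous for a reporter in which green fluorescent protein (GFP) reads out the chemokine gene Cxcl2, on the C57BL/6 background. CD45-positive cells were enriched with magnetic beads. There were 2 libraries, each from a pool of 3 mice: a naive library, and an infected library made 9 h after oro-tracheal delivery of 10000 Cryptococcus neoformans yeasts per mouse. Each group thus had 1 library, so no test, p-value or standard error was computed, and cells were not treated as replicates.

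The deposited matrices hold whole-number UMI counts per gene and barcode, without normalization. The submitters' processing notes name Cell Ranger 3.0.1 and the mm10 genome for these counts. The matrices list 31054 features, of which 31053 are Ensembl genes and 1 is the GFP transcript. A total of 71 features carry a gene symbol that another feature also has, and genes were followed by identifier. Gene positions came from GENCODE M21, whose build GRCm38 is mm10. The naive matrix holds 4976 barcodes and 46741731 UMIs, and the infected matrix holds 6050 barcodes and 50525398 UMIs. The lowest barcode in each matrix had 500 UMIs.

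Barcodes with at least 500 UMIs, at least 200 genes and at most 10% mitochondrial UMIs were kept. In the naive library 46 barcodes had fewer genes and 167 exceeded the mitochondrial limit, which left 4808. In the infected library the corresponding numbers were 92 and 226, which left 5819. Doublets were called in each library with Scrublet at an expected rate of 5%. The calls removed 15 naive barcodes (0.312%, a low rate for this loading) and 120 infected barcodes (2.06%), and the lower of both thresholds would have removed 68 naive barcodes (1.41%). The kept cells numbered 4793 with a median of 6321 UMIs, 2013 genes and 3.46% mitochondrial UMIs in the naive library. They numbered 5699 with a median of 5264 UMIs, 1597 genes and 2.83% mitochondrial UMIs in the infected library.

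Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes, without immunoglobulin and T-cell-receptor variable genes, gave 30 principal components and a graph of 15 neighbours, which Leiden clustering at resolution 1.0 and seed 0 divided into 29 clusters, both libraries together and without integration. Clusters were named from 160 markers of 22 cell types. A cluster took the type whose markers had the highest mean z-score over clusters, provided that the score exceeded 0.5 and at least 3 of the markers were detected in at least 25% of its cells. It stayed unnamed when another type had more markers among its 10 leading genes, when it was shallow and none of its own markers was among them, or when over 25% of its cells held UMIs of at least 3 B cell markers and at least 3 markers of T cells, natural killer cells or neutrophils. These naming limits were set after the clusters had been seen. A total of 24 clusters were named and 5 were not, which left 9.76% of naive and 5.79% of infected cells without a name. Names carry the ending -like because they rest on transcripts alone. The reference-based annotation that the submitters describe for alveolar macrophages was not used. The mice of a pool are not labelled, so cells were called male when they held a UMI of Ddx3y, Eif2s3y, Kdm5d or Uty and none of Xist, and female in the reverse case.

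For each class with at least 50 cells in both libraries, UMIs were summed over its cells in each library and expressed as CPM, the UMIs of a gene scaled to a common class total. The log2 ratio of infected over naive was taken with its exact conditional binomial 95% interval, for genes with at least 20 UMIs over both sums. Shares of cells carry exact Clopper-Pearson 95% intervals, and all intervals cover counting error only. Values for genes with 0 UMIs on one side were bounded with a floor of 3 counts per sum.

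A set of 21 gene lists was written down before the data were examined, as were the markers, the comparisons, the rule for naming genes and 45 alternative settings. The lists hold 286 members, of which 284 matched the features. They are neutrophil chemoattractants (CXC ligands of CXCR2), CC chemokines, inflammatory cytokines and NF-kB targets, type I interferon-stimulated genes, interferon-gamma-induced GTPases and partners, complement and C1q, alternative activation and anti-inflammatory genes, fungal and pattern recognition receptors, alveolar macrophage identity, surfactant and lipid handling, immediate-early and dissociation stress, glycolysis and hypoxia, nuclear oxidative phosphorylation, metal, iron and oxidative stress response, cell cycle, MHC class II and costimulation, MHC class I and peptide loading, lysosome and phagocytosis, neutrophil maturation and granules, lymphocyte activation, and sex-linked genes. The result of a list is its median log2 ratio. An interval for the median came from 1000 Poisson redraws of the sums. Its percentile among 10000 random lists of the same size and matched expression is a description of these libraries, not a test. Members 1.5-fold or more apart were counted. Of the identity list, Marco, Siglecf, Car4, Fabp1, Krt79, Ear1, Plet1, Atp6v0d2, Cidec and Lpl had also served to name the alveolar macrophage-like class.

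Genes were named by a fixed size rule: at least 50 CPM in either library and at least 2-fold apart, ranked by the bound of the interval nearest to no change. The rule takes the 12 highest and 12 lowest genes in alveolar macrophage-like cells, 5 each way in other classes, and 10 each way between Cxcl2-positive and Cxcl2-negative cells. It leaves out unnamed gene models, mitochondrial, ribosomal, haemoglobin, immunoglobulin and T-cell-receptor genes. Up to 4 members of each list were named in addition, and Cxcl2, Cxcl1, C1qa, C1qb, C1qc, Il1b, Tnf, Siglecf and Marco always. GFP, and members beyond that number, were chosen after their values were seen.

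For shares of cells with Cxcl2 UMIs, every alveolar macrophage-like cell was thinned to 9000 UMIs. This depth is the 25th percentile of the shallower library, rounded down to a multiple of 500, and shallower cells were left out. Cells with at least 1 Cxcl2 UMI after thinning were compared with cells at 0 in each library, with Cxcl2 removed from the lists.

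The ratio and list steps were tested on simulated data in which known folds were planted into the alveolar macrophage-like sums of 11103 genes. The simulated sums were Poisson draws from 1 pooled profile, which is the counting error that the intervals assume. They thus check the computation only, and hold no variation between cells or mice. The intervals held the planted value for 95.6% of unchanged genes, 94.0% of genes planted 2-fold higher and 90.0% of genes planted 4-fold higher, with median log2 ratios of 0.99 and 2.01 for the planted sets. For genes planted 2-fold and 4-fold lower the intervals held the value for 96.0% each, with medians of -1.03 and -2.01. A planted list of 15 genes at 1.5-fold had a median of 0.58 and reached percentile 100, and 5.5% of 200 unchanged lists lay outside the central 95%.

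The alternatives covered doublets, mitochondrial and UMI limits, clustering resolution and seed, a gate on markers in place of clusters, scaling, the minimum of UMIs per gene, thinning and the Cxcl2 limit, and 20 more were chosen after seeing the data. Scaling by the median ratio over genes shifts every log2 ratio of a class by 1 constant, and the median over measured genes under the scaling used here was -0.08 in alveolar macrophage-like cells, -0.12 in neutrophil-like cells and -0.10 in nonclassical monocyte-like cells. The software was Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.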

Results

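At 9 h after delivery of the yeast, neutrophils made up a much larger part of the lung leukocytes than in naive mice, and alveolar macrophages a smaller part. Neutrophil-like cells rose from 13.1% (95% interval 12.2 to 14.1; 628 cells) of the naive library to 38.0% (36.7 to 39.2; 2164 cells) of the infected library, a 2.90-fold higher share. The rise was unequal by sex, from 153 to 249 cells called male and from 57 to 422 called female, with 418 naive and 1493 infected neutrophil-like cells uncalled. Alveolar macrophage-like cells, the resident phagocytes of the air spaces, made up 18.5% (17.4 to 19.6; 887 cells) of the naive and 10.5% (9.71 to 11.3; 598 cells) of the infected library, 1.76-fold lower. Shares within a library sum to a fixed total, so the classes were also taken over non-neutrophil cells. There alveolar macrophage-like cells went from 21.3% (20.1 to 22.6) to 16.9% (15.7 to 18.2).

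B cell-like cells fell from 20.4% (19.3 to 21.6) to 14.97% (14.1 to 15.9) of all cells, but stood at 23.5% and 24.1% of non-neutrophils. T cell-like cells went from 8.88% to 13.4% of non-neutrophils, and classical monocyte-like cells, the Ly6c2-bearing blood monocytes, from 4.32% to 7.27%. Nonclassical monocyte-like cells (5.76% and 5.63%), natural killer cell-like cells (4.37% and 4.47%) and interstitial macrophage-like cells (4.78% and 4.24%) held closer shares of the non-neutrophils. Conventional dendritic cell 2-like cells, which present antigen to helper T cells, went from 5.64% to 4.07%, and conventional dendritic cell 1-like cells, which cross-present antigen, from 3.72% to 3.31%. Migratory dendritic cell-like cells, named from Ccr7 and Fscn1, rose from 0.501% (0.321 to 0.744; 24 cells) to 1.21% (0.943 to 1.53; 69 cells) of all cells. No group was given the oro-tracheal delivery without yeast. Loading, cell recovery, the delivery itself and the mice of a pool thus cannot be separated from infection for any share.

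**Figure D1:**
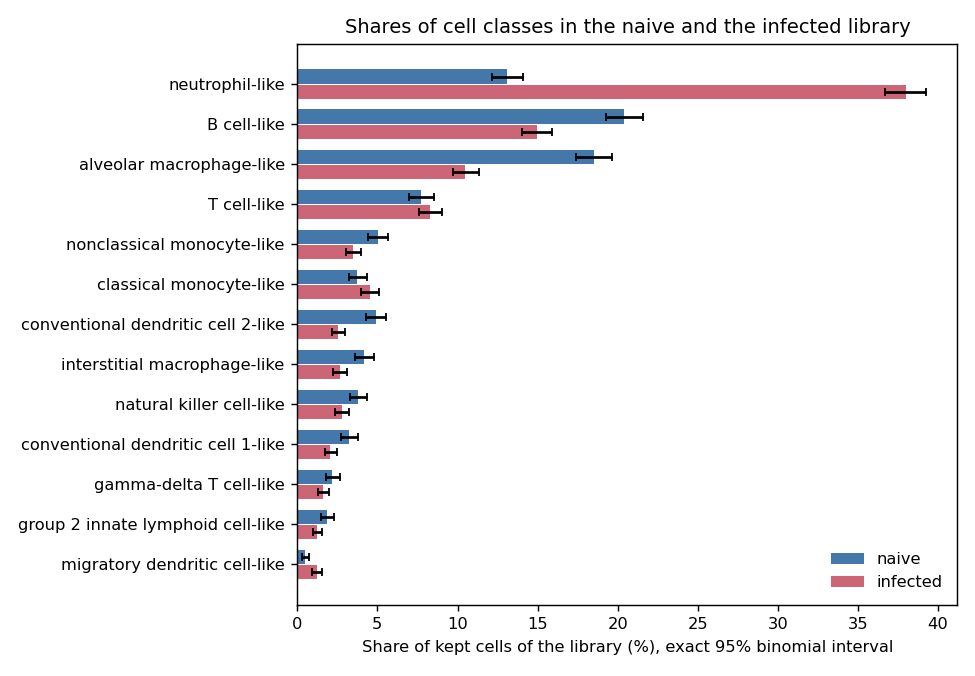
Share of kept cells (%, horizontal axis) for each class with at least 50 cells over both libraries, with naive in blue, infected in red and exact 95% binomial intervals as lines. Neutrophil-like cells stand at 13.1% in the naive and 38.0% in the infected library, and alveolar macrophage-like cells at 18.5% and 10.5%.

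Alveolar macrophage-like cells of the infected library carried an inflammatory and neutrophil-recruiting transcript profile. Chemokines that draw neutrophils through CXCR2 were far higher, together with Il1b, the acute-phase genes Lcn2 and Cfb, and the yeast-sensing lectin Clec4e. The neuropeptide gene Gal was lower. The class fell into different clusters in the libraries: 1 cluster held 72.8% of naive but 24.1% of infected cells of the class, and another held 1.58% and 58.4%. The values below are sums over all clusters of the class.

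Cxcl3, at chromosome 5 positions 90786103 to 90789600 of mm10 (ENSMUSG00000029379), rose from 22.5 to 2815 CPM, a log2 ratio of 6.97 (6.79 to 7.15) or 125-fold. It was seen in 53 of 887 naive and 339 of 598 infected cells. Cxcl2, a nearby gene of the same chemokine cluster (ENSMUSG00000058427, positions 90903871 to 90905938), was already abundant in naive cells and rose 2.58-fold, from 1726 to 4460.0 CPM, a log2 ratio of 1.37 (1.34 to 1.39). Cxcl1 (positions 90891241 to 90893115) rose 6.03-fold, from 66.6 to 402. The reporter GFP rose 1.79-fold, from 956 to 1709.6. Il1b, the gene of the pyrogenic cytokine IL-1β on chromosome 2 (129364570 to 129371139), rose from 92.2 to 1000.2 CPM, 10.9-fold, and was seen in 287 naive and 461 infected cells. Tnf moved less, from 51.8 to 71.5, a log2 ratio of 0.46.

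Inhba (chromosome 13, 16011851 to 16031621), which encodes the activin A subunit, rose from 3.55 to 250.4 CPM (log2 6.14). Wfdc17, a secreted protease-inhibitor family member, rose from 70.8 to 1531, and the chemokine Ccl9 from 68.7 to 1428. Cfb (chromosome 17, 34856374 to 34862518), factor B of the alternative complement pathway, rose from 9.05 to 156, and Clec4e (chromosome 6, 123281789 to 123289870), the receptor Mincle, from 28.1 to 314. Lcn2, whose product binds bacterial siderophores, rose from 2.39 to 57.8, the aminopeptidase gene Anpep from 1.69 to 74.3, the NF-kB-regulated gene AA467197 from 5.77 to 232, and the membrane protease gene Mmp14 from 0.443 (5 UMIs) to 50.2. Ccl17, which attracts T cells, rose from 9.40 to 207, but 36.6% of its infected UMIs lay in 3 cells. Marco (chromosome 1, 120474538 to 120505024), a scavenger receptor that binds microbes, rose 4.32-fold from 508 to 2198.

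Gal (chromosome 19, 3409915 to 3414544), which encodes galanin, fell from 113 to 8.91 CPM, a log2 ratio of -3.67 (-4.00 to -3.35). Selenop, which encodes the plasma selenium carrier, fell from 358 to 132, and Apoc1, a lipoprotein component, from 56.7 to 20.01. Tppp3, a tubulin-binding protein gene, fell from 199 to 46.9, the leukocyte cytoskeletal gene Lsp1 from 723 to 272, the protease-inhibitor gene Serpinb1a from 185 to 69.3, and the stress-linked gene Fam129a from 339 to 133. Rnase4, Cpne5 and Kazald1 fell by 1.96, 1.69 and 1.53 on the log2 scale. Scgb1a1, an airway secretory cell transcript, went from 74.8 to 24.0. Its log2 ratio turned to 0.31 when barcodes under 1000 UMIs were left out and the rest were clustered and named again. Siglecf, a surface lectin that marks alveolar macrophages, went from 159 to 77.9. The C1q genes, which start the classical complement pathway, went from 9.40 to 2.10 for C1qa, from 14.1 to 2.62 for C1qb and from 6.74 to 1.68 for C1qc. Of the naive C1qa UMIs, 79.2% lay in 3 cells. The class II gene H2-Eb1 fell from 197 to 17.7 and is treated with the sexes.

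**Figure D2:**
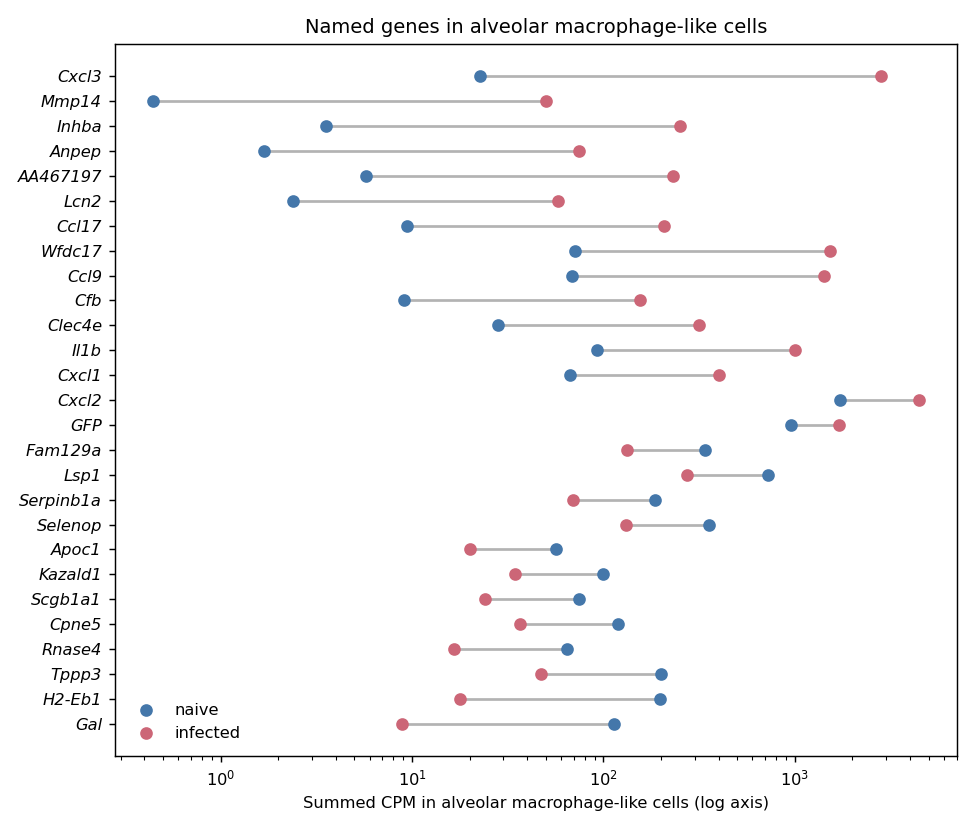
Summed CPM in alveolar macrophage-like cells (horizontal log axis) for the 24 genes taken by the fixed size rule plus Cxcl1, Cxcl2 and GFP, with naive in blue and infected in red. Cxcl3 moves from 22.5 to 2815 and Gal from 113 to 8.91.

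Across the fixed lists, the neutrophil chemoattractants had the highest median in alveolar macrophage-like cells, 2.59 on the log2 scale (2.48 to 2.71), with 3 of 3 measured members at least 1.5-fold higher. CC chemokines, which recruit monocytes and lymphocytes, had a median of 1.12 (0.94 to 1.32), with Ccl3 going from 220.0 to 625 and Ccl4 from 51.3 to 139.5 CPM. The inflammatory cytokines and NF-kB targets had a median of 0.69 (0.59 to 0.81), with 12 of 22 members at least 1.5-fold higher and 2 lower. Il1a rose from 57.0 to 241, the mitochondrial superoxide dismutase gene Sod2 from 114 to 648 and the NF-kB inhibitor gene Nfkbia from 393 to 916, while Cd83 went from 89.9 to 52.4. Fungal and pattern recognition receptors had a median of 0.56, with 7 of 15 higher and 0 lower, among them Clec4d (26.4 to 81.5) and the kinase gene Syk (235 to 419). Each of these lists stood at percentile 100 of its matched random lists.

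The metal, iron and oxidative stress list had a median of 0.66 (percentile 100, 8 of 14 higher). Its members included the iron-storage gene Fth1, which rose from 12328 to 34584, the cystine transporter gene Slc7a11, from 26.7 to 209, and the haem-degrading enzyme gene Hmox1, from 184 to 552. Glycolysis and hypoxia genes had a median of 0.32 (percentile 99.96), with the glucose transporter gene Slc2a1 going from 8.69 to 23.2 and Hk2 from 68.3 to 116. Nuclear oxidative phosphorylation genes stood at -0.06 (0 of 15 apart by 1.5-fold) and at 0.02 when scaled by the median ratio. MHC class I and peptide loading had a median of 0.22 (percentile 98.7) and lysosome and phagocytosis 0.15 (percentile 99.2), with Lyz2 going from 11821 to 16355. The lysosome and phagocytosis median was -0.04 in male and 0.24 in female cells.

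Interferon-linked lists rested on low counts in these cells. Type I interferon-stimulated genes had a median of 1.23 (10 of 14 higher, 2 lower), with Isg15 going from 9.05 to 29.1 CPM. The medians were -0.10 in male cells, over 7 measured members, and 1.54 in female cells, over 12. They thus do not compare the same genes, and the male interval ran from -0.46 to 0.33. Interferon-gamma-induced GTPases and partners had a median of 0.56 (5 of 10 higher), with Gbp2 going from 18.8 to 65.4. Neutrophil maturation and granule genes had a median of 1.36 (7 of 12 higher, 3 lower), which turned to -0.38 when cells were weighted equally. Of that list, 62.1% of the infected S100a8 UMIs lay in 3 cells.

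Lists on the lower side included MHC class II and costimulation, with a median of -0.93 (-1.04 to -0.86) and 7 of 10 members lower. H2-Aa went from 245 to 98.5 and the invariant chain gene Cd74 from 728 to 344 CPM. The sexes moved apart, with H2-Aa going from 74.9 to 161 in male but from 156 to 55.2 in female cells, and H2-Ab1 from 77.4 to 161 and from 158 to 79.8. Of the 2759 naive H2-Aa UMIs, 238 lay in male and 1093 in female cells, and the rest in 192 cells called neither. The fall over all cells thus rests in part on cells without a called sex, since the naive level of 245 CPM lay above that of either sex. Cells with both Y-linked and Xist UMIs, as a doublet of both sexes would have, were also called neither. Their number was not examined, so part of the naive class II level may come from other cells. The list median was -0.15 in male and -0.98 in female cells. Under a gate on markers in place of clusters it was 0.39, so its direction depended on how cells were chosen. Complement and C1q had a median of -1.24, with C3 and Cfb higher and 5 of 7 lower. It was positive under the marker gate (1.36) and among male cells (0.33, over 4 measured members). Immediate-early and dissociation stress genes had a median of -0.39 (percentile 0.01, 7 of 17 lower), with Fos going from 1764 to 985 and Egr1 from 234 to 107. Cell cycle genes stood at -0.29 (percentile 1.82), and at 0.09 with cells weighted equally. Alternative activation and anti-inflammatory genes stood at -0.23, with Retnla going from 48.6 to 0.838 but Il1rn, the interleukin-1 receptor antagonist, from 213 to 433. That median was 0.03 with doublets kept.

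The alveolar macrophage identity list stood at -0.17 (percentile 5.75), with 4 of 17 higher and 3 lower. The identity gene Car4 rose from 438 to 2361 while Fabp1 fell from 759 to 348 and Cidec from 384 to 176. Surfactant and lipid handling stood at 0.03 (percentile 87.2), with Csf2rb going from 372 to 724 and the cholesterol exporter gene Abcg1 from 1236 to 787. The median was -0.01 under the 5% mitochondrial limit. Lymphocyte activation genes stood at -0.13 (percentile 37.5) and sex-linked genes at -0.29 (percentile 14.1). All 12 higher and all 12 lower named genes were at least 2-fold apart among male cells (226 naive, 145 infected) and among female cells (469 naive, 352 infected) taken separately. The genes were picked from sums that include these cells, so this is no independent check. The neutrophil chemoattractant medians were 2.85 in male and 2.56 in female cells, and the inflammatory medians 0.92 and 0.72. Other lists lay further apart by sex, with CC chemokines at 2.11 in male and 0.99 in female cells, neutrophil granules at 0.45 and 1.98, and lymphocyte activation at -0.91 and 0.12.

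**Figure D3:**
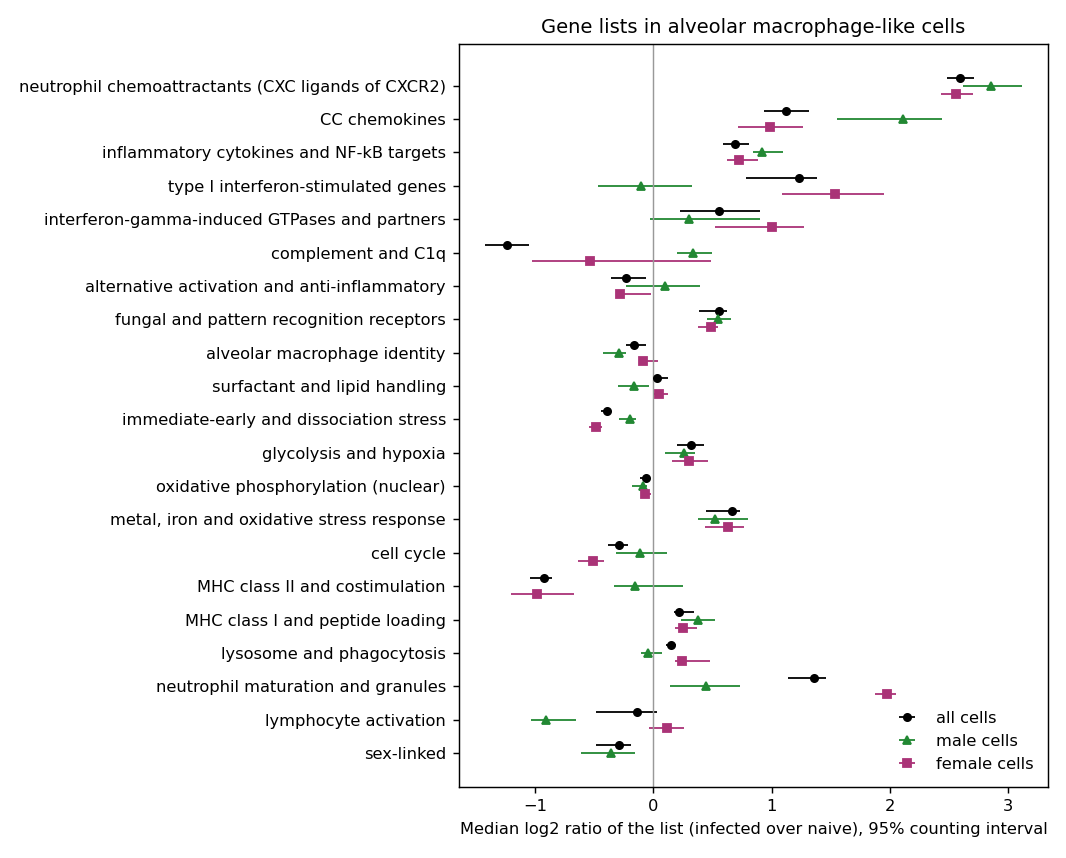
Median log2 ratio of infected over naive (horizontal axis) for the 21 lists in alveolar macrophage-like cells, for all cells and for male and female cells, with 95% counting intervals. Neutrophil chemoattractants lie at 2.59 over all cells, while type I interferon-stimulated genes lie at -0.10 in male (7 measured members) and 1.54 in female cells (12 measured members).

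Neutrophil-like cells of the infected library carried more chemokine and cytokine RNA and more transcripts of sugar use. Cxcl2 rose from 15538 to 38395 CPM and Ccl3, a macrophage inflammatory chemokine, from 98.5 to 1239.5. Il1a rose from 6.47 to 157, Wfdc17 from 419.9 to 2551 and Spp1, which encodes osteopontin, from 74.4 to 519.96. Fmnl2, a formin that builds actin filaments, went from 0.925 (2 UMIs) to 55.1. Il1b changed little, from 10361 to 11229. The neutrophil chemoattractant median was 1.31, the inflammatory median 0.81 (11 of 21 higher, 1 lower) and the glycolysis and hypoxia median 0.60 (7 of 13 higher), with the lipid-droplet gene Hilpda going from 41.2 to 155. Nuclear oxidative phosphorylation stood at -0.49 and type I interferon-stimulated genes at -0.74 (10 of 19 lower), with Isg15 going from 645 to 385 and Irf7 from 223 to 104. Scgb1a1 and the monocyte-linked genes Ms4a6c, Ms4a4c and S100a4 were lower, by log2 ratios of -3.36, -3.41, -3.19 and -3.04. The last 3 were each seen in under 5% of cells, and Lyz1 rested on 2 naive and 4 infected cells.

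The neutrophils of the libraries differed in make-up. One cluster held 66.6% of naive and 32.3% of infected neutrophil-like cells, another 24.2% and 32.9%, and another 0.796% and 31.4%. A cluster led by interferon-stimulated genes held 8.44% and 3.47%, and without it the type I interferon-stimulated median of the class was -0.10. Of the cells assignable to a sex, 72.9% (66.3 to 78.7) were male in the naive and 37.1% (33.4 to 40.9) in the infected library. The other 11 compared classes were 15.4% to 37.5% male in the naive and 19.4% to 40.9% in the infected library. Among male cells alone the inflammatory median was 0.53.

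Both monocyte classes shifted toward inflammatory and alternative-activation transcripts. In nonclassical monocyte-like cells, which patrol vessel walls, Cxcl3 rose from 20.6 to 662 CPM, Csf1, the macrophage growth factor, from 8.25 to 185, AA467197 from 9.74 to 187 and Il1a from 1.499 to 90.2. Their Cxcl2 rose from 2065 to 13046, Il1b from 1058 to 4064 and Il1rn from 36.4 to 544.5. The neutrophil transcript S100a8 rose in the same class from 3249.8 to 10104, against 71432 in infected neutrophil-like cells, and the part of these rises that came with neutrophil RNA was not measured. Their inflammatory median was 1.07 (16 of 20 higher), the alternative activation median 1.90 (8 of 12 higher, but 0.38 in female cells) and the pattern recognition median 1.32. In classical monocyte-like cells, Spp1 rose from 2.44 to 544 and the acute-phase gene Saa3 from 3.90 to 383, with 59.9% and 53.7% of infected UMIs in 3 cells. AA467197 rose there from 0.975 to 244 and the endocytic adaptor gene Dab2 from 0.487 (1 UMI) to 106. Ccl24 rose from 2.92 to 245 with 71.3% of infected UMIs in 3 cells. Arg1, the arginase of alternatively activated macrophages, rose from 5.36 to 327, C1qb from 12.2 to 219 and H2-Aa from 412 to 734. The classical monocyte medians were 0.65 for inflammatory genes (11 of 21 higher; 0.30 in male and 0.96 in female cells), 2.62 for complement and C1q (6 of 8 higher), 1.44 for alternative activation and -0.59 for type I interferon-stimulated genes (9 of 18 lower). The lower named genes included the B cell transcripts Cd79a, Ebf1 and Ly6d in both classes, with Cd79a at -1.90 and -2.69 on the log2 scale. The others were Ms4a1 and H2-Eb1 in the nonclassical class, and H2-T23 and Tmcc3 in the classical class. The nonclassical Saa3 rise rested on 4 cells.

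Interstitial macrophage-like cells, which live in the lung tissue, had a small inflammatory median of 0.16 but higher interferon-stimulated (1.10, 11 of 18 higher), glycolysis (0.79) and metal and oxidative stress (0.78) medians. Isg15 rose there from 27.6 to 99.3 CPM, Hmox1 from 211 to 1007 and Cxcl2 from 10507 to 14338. The B cell attractant gene Cxcl13 rose from 18.8 to 1046, with 73.4% of the UMIs in 3 cells, and Timp1 and Lcn2 rose by 5.47 and 3.16 on the log2 scale, with 54.8% and 70.6% of the UMIs in 3 cells. Plac8 fell from 128 to 10.2, the phospholipase gene Pla2g2d from 92.3 to 23.6 and Cd28 from 67.9 to 17.1. In conventional dendritic cell 2-like cells, the metalloproteinase inhibitor gene Timp1 rose from 4.31 to 63.2 and the adhesion gene Cdh1 from 4.09 to 55.8, while Egr1 fell from 166 to 45.9. The interferon-inducible gene Ifitm1 rose there from 22.9 to 245, with 45.9% of infected UMIs in 3 cells. Retnla fell from 1678 to 182, but was seen in 26 naive and 15 infected cells. In conventional dendritic cell 1-like cells, Cxcl9, an attractant of activated T cells, rose from 4.29 to 66.9, with 74.1% of the UMIs in 3 cells. Alveolar macrophage transcripts were lower there, with Chil3 going from 464 to 26.3 and an identity list median of -2.04, though 52.6% of the naive Chil3 UMIs lay in 3 cells.

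T cell-like cells raised the cytokine-signal inhibitors Socs3 (82.2 to 282 CPM) and Socs1 (44.3 to 101), the STAT3-linked gene Sbno2 (52.7 to 119) and Gadd45g (12.9 to 50.3). In gamma-delta T cell-like cells, Il17a, whose product drives neutrophil responses, rose from 183 to 926, a log2 ratio of 2.34 (2.07 to 2.62), seen in 28 of 105 naive and 38 of 93 infected cells, with 38.9% and 35.7% of its UMIs in 3 cells. Their lymphocyte activation median was 0.66 (7 of 10 higher). In B cell-like cells, the heat-shock gene Hspa1a rose from 84.2 to 182, and Cxcl2, S100a8 and S100a9 rose from 37.9 to 118, 26.2 to 79.6 and 35.0 to 97.9, levels far below those of neutrophil-like cells. Inflammatory medians were 0.22 in T cell-like, 0.06 in B cell-like and 0.01 in natural killer cell-like cells. Scgb1a1 was lower in each of these 3 classes, for example from 66.3 to 5.39 in B cell-like cells. In natural killer cell-like cells the higher genes were Map3k14, Pmepa1, Nrgn, Dera and Grcc10, between 1.05 and 1.24 on the log2 scale. In group 2 innate lymphoid cell-like cells, Ccl17, Ccl22, Spp1 and Plet1 were higher but seen in at most 3 infected cells, and 91.0% of the infected Cst3 UMIs lay in 3 cells.

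A larger share of alveolar macrophages held Cxcl2 in the infected library, and the counts per cell were shifted upward with wide overlap. At 9000 UMIs per cell, 78.9% (75.6 to 81.9) of 668 naive and 92.9% (90.3 to 94.998) of 509 infected cells had at least 1 Cxcl2 UMI, and 219 naive and 89 infected cells were too shallow to count. Without thinning the shares were 78.6% and 92.3%, at median depths of 13602 and 16647 UMIs. The median was 6 Cxcl2 UMIs per naive cell, with quartiles of 1 and 20, and 22 per infected cell, with quartiles of 7 and 51. Cells with at least 10 UMIs made up 41.3% (37.6 to 45.2) and 67.6% (63.3 to 71.6). The counts formed a range without a gap, and 14.7% of naive and 8.06% of infected cells sat at 1 or 2 UMIs, so a class made on this 1 gene is a range, not a type.

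B cell-like cells, which should lack Cxcl2, gave the background. At least 1 UMI was found in 12.4% (10.4 to 14.6) of naive and 44.9% (41.5 to 48.3) of infected B cell-like cells, at median depths of 4269 and 4324 UMIs, which is 0.1996 and 0.641 UMIs per cell against 21.9 and 71.2 in alveolar macrophage-like cells. Shares at 1 UMI thus carry a higher background in the infected library, whose source was not tested. Of the naive and infected B cell-like cells, 0.102% and 0.0% reached 10 UMIs. GFP was found in 68.3% (64.6 to 71.8) of naive and 80.7% (77.0 to 84.1) of infected alveolar macrophage-like cells, against 3.28% and 5.04% of B cell-like cells. Across alveolar macrophage-like cells, which are not replicates, Cxcl2 and GFP UMIs had a Spearman correlation of 0.882 in the naive and 0.864 in the infected library. GFP per 100 Cxcl2 UMIs went from 55.4 to 38.3. Neutrophil-like cells held 30.02% of all naive and 71.7% of all infected Cxcl2 UMIs, and alveolar macrophage-like cells 17.4% and 8.32%.

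**Figure D4:**
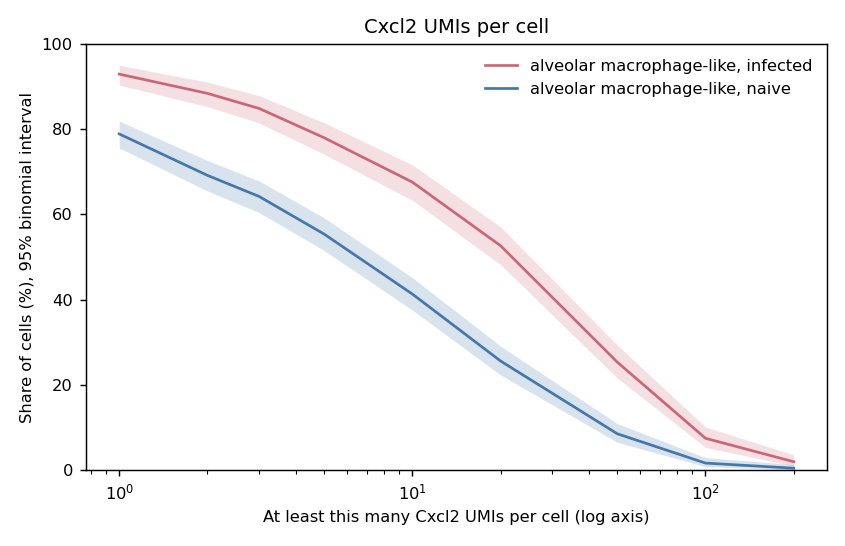
Share of alveolar macrophage-like cells (%, vertical axis) with at least a given number of Cxcl2 UMIs (horizontal log axis) after thinning to 9000 UMIs, with 95% binomial intervals shaded. The infected curve runs from 92.9% at 1 UMI to 67.6% at 10, above the naive curve at 78.9% and 41.3%.

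Within each library, alveolar macrophages with Cxcl2 carried more inflammatory transcripts than those without. They also carried more of the immediate-early and dissociation stress list. In the naive library (527 cells with and 141 without), the immediate-early median was 0.84 (0.76 to 0.93; 14 of 17 higher), the inflammatory median 0.54 (0.39 to 0.74; 9 of 20 higher) and the cell cycle median -0.85 (8 of 11 lower). In the infected library (473 with, 36 without), the inflammatory median was 1.07 (0.68 to 1.37; 13 of 21 higher), the CC chemokine median 1.59 (1.36 to 2.09) and the immediate-early median 0.60 (10 of 17 higher). The cell cycle median was 0.37 there (0.09 to 0.93; 4 of 11 higher, 1 lower), opposite to the naive library. The small number of cells without Cxcl2, and the higher background, limit this split most in the infected library. Whether the Cxcl2 of these cells arose in the lung or during dissociation was not tested in either library.

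In the naive library GFP went from 33.1 CPM in cells without Cxcl2 to 1218 in cells with it, and Cxcl1 from 13.4 to 79.1. The transcription factor genes Jun (276 to 891), Egr1 (92.2 to 283) and Klf2 (118 to 367), the heat-shock genes Hspa1a (22.9 to 124) and Hspa1b (7.88 to 113) and the signalling regulator gene Rgs1 (80.4 to 275) were higher. The neutrophil transcripts S100a9 (25.2 to 95.7) and S100a8 (36.2 to 84.97) were higher too, with 26.2% of the S100a9 UMIs of Cxcl2-positive cells in 1 cell. Genes of dividing cells were lower, with Ube2c going from 89.8 to 21.7, Top2a from 130.02 to 58.6, Mki67 from 134 to 61.1 and Birc5 from 78.8 to 29.7. In the infected library GFP went from 18.5 to 1739 (6 UMIs in cells without Cxcl2), Cxcl3 from 105 to 2664, Cxcl1 from 9.26 (3 UMIs) to 400.3 and Inhba from 12.3 to 240.1. Ch25h, which makes the immune-active sterol 25-hydroxycholesterol, went from 37.0 to 306 and Il1b from 176 to 991. Ccl4 had 0 UMIs in cells without Cxcl2 and 139.8 CPM in cells with it. The keratin gene Krt19 went from 611 to 255 and the adhesion gene Cd2 from 253 to 122. Marco differed in the infected library (1213 to 2213) more than in the naive library (485 to 509).

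H2-Eb1 (chromosome 17, 34305867 to 34316674), which encodes a chain of a class II molecule, was followed by sex in the other antigen-presenting classes after its values were seen. In B cell-like cells of the infected library it made up 2.54% of the H2-Aa, H2-Ab1 and H2-Eb1 UMIs in male cells and 24.3% in female cells, against 33.5% and 28.5% in the naive library. The infected male and female shares were 1.32% and 27.1% in conventional dendritic cell 2-like cells, 0.955% and 25.5% in conventional dendritic cell 1-like cells and 2.35% and 26.9% in interstitial macrophage-like cells. In alveolar macrophage-like cells they were 2.79% and 12.1%, against 22.3% and 28.1% in the naive library.

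**Figure D5:**
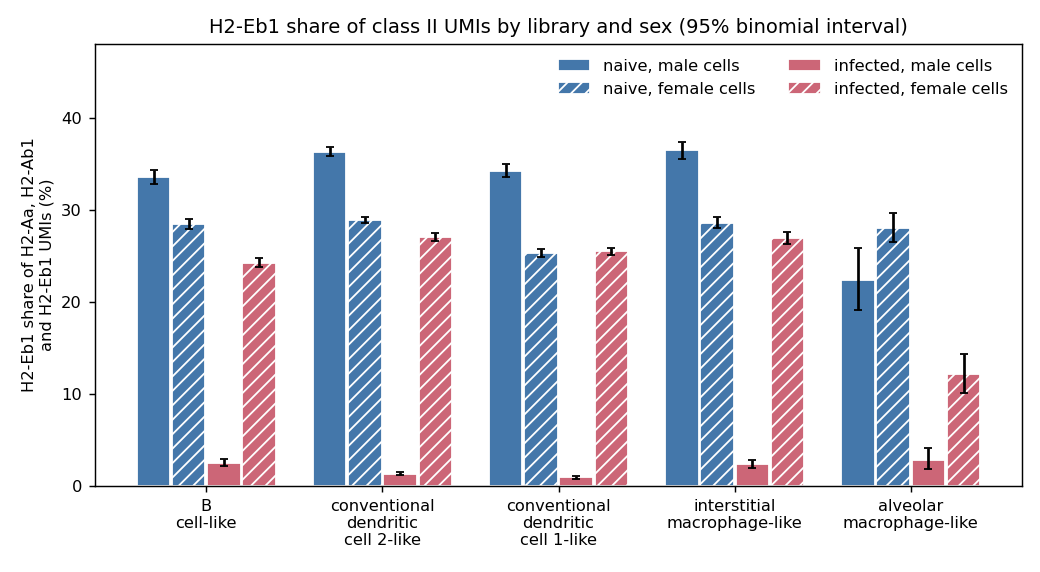
H2-Eb1 share of the H2-Aa, H2-Ab1 and H2-Eb1 UMIs (%, vertical axis) by class, library and sex of the cells, with 95% binomial intervals; plain bars are male and hatched bars female cells. Male cells of the infected library lie between 0.955% and 2.79%.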

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

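Of the tests in this part, that on neutrophil RNA and those on H2-Eb1 were chosen only after the result was seen. A list drew a closer look when its log2 medians in alveolar macrophage-like cells and another class had opposite signs, each at least 0.5 in size. This screen covered 190 pairs of class and list, without the sex-linked list. Both medians needed at least 5 measured members and a counting interval that excluded 0. The same rule over 18 pairs of male and female medians of alveolar macrophage-like cells flagged nothing. None of the flagged differences was tested, since each class has 1 library per group. Type I interferon-stimulated genes stood at 1.23 in alveolar macrophage-like cells, against -0.74 in neutrophil-like and -0.59 in classical monocyte-like cells. In male cells the value was -0.10 in place of 1.23, over 7 measured members against 12 in female cells. The -0.74 moved to -0.10 without the neutrophil-like cluster led by these genes. Interferon-gamma-induced GTPases and partners stood at 0.56, against -0.55 in neutrophil-like and -0.56 in conventional dendritic cell 2-like cells. Neutrophil maturation and granule genes stood at 1.36, against -0.85 in T cell-like and -0.90 in natural killer cell-like cells. The 1.36 turned to -0.38 with cells weighted equally, and 3 cells held 90.5% of the naive S100a9 UMIs of T cell-like and 90.4% of those of natural killer cell-like cells. Without the 3 leading cells of each library, S100a9 stood at 0.83 and 0.60 there, opposite to its sums over all cells. Complement and C1q stood at -1.24, against 0.52 in nonclassical and 2.62 in classical monocyte-like cells, and the -1.24 turned to 1.36 under the marker gate. MHC class II and costimulation stood at -0.93, against 0.62 in classical monocyte-like and 1.90 in group 2 innate lymphoid cell-like cells. The -0.93 turned to 0.39 under the marker gate. In the infected group 2 innate lymphoid cell-like class 3 cells held 91.0% of the UMIs of Cst3, a gene abundant in dendritic cells, whose log2 ratio was 0.04 without the 3 leading cells of each library. Between the highest and lowest tertile of alveolar macrophage-like cells by Cxcl2, cell cycle genes stood at 1.04 in the infected and -1.06 in the naive library, the only such difference among 37 pairs of splits, which was not tested either.

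The Cxcl2 level of alveolar macrophage-like cells was higher in the infected library, where neutrophil-like cells held 71.7% of all Cxcl2 UMIs. Doublets with neutrophils, or their free RNA, would have brought their S100a8 along, but the S100a8 excess of 3.69 UMIs per cell was 4.03% of the 91.6 needed, and that of S100a9 was 3.37%. This need takes the mean S100a8 to Cxcl2 ratio of all infected neutrophil-like cells, 1.86. RNA with a lower ratio would need less, and infected B cell-like cells held 79.6 CPM of S100a8 against 118 of Cxcl2. Needs at other ratios were not computed. A different sex composition of the pools is argued against by the fold, whose smaller value over male and female cells taken apart was 2.59. A response of the macrophages to the yeast may account for the rise, as a hypothesis. An effect of the oro-tracheal delivery itself cannot be told apart from one of the yeast, since no group was given the delivery alone. A difference between the 3 mice of each pool, or between the libraries in any step that acted on this class alone, stays open.

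The inflammatory cytokine and NF-kB target list was higher in infected alveolar macrophage-like cells. A difference in handling or dissociation across the library, as the whole cause, is argued against by the immediate-early list in lymphocytes, whose median farthest from 0 over B cell-like, T cell-like and natural killer cell-like cells was 0.21, and which stood at -0.39 in alveolar macrophage-like cells. Library-wide differences did exist, since its member Hspa1a went from 84.2 to 182 CPM in B cell-like and from 137 to 281 in T cell-like cells. Ldha, Lars2 and Hist1h1e moved the same way in all 12 compared classes. The airway secretory cell transcript Scgb1a1 had log2 ratios of -3.62 in B cell-like, -2.30 in T cell-like and -3.36 in neutrophil-like cells. Free RNA of other cells may thus differ between the libraries, which was not tested. Sex composition is argued against by the list median, whose smaller value over male and female cells was 0.72. A macrophage response to infection could explain the list, as a hypothesis, and differences between the pooled mice or a partial share of handling stay open. The oro-tracheal delivery itself stays open too, without a group given it alone.

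H2-Eb1 was lower in antigen-presenting classes of the infected library. A general decrease of class II transcripts is argued against by H2-Aa and H2-Ab1, since H2-Eb1 lay below the lower of both by at least 0.68 on the log2 scale in B cell-like, interstitial macrophage-like and both conventional dendritic cell classes. Mice of different genotype within the pools are a candidate explanation: the male share of H2-Eb1 was at most 10.5% of the female share in the infected library over these 4 classes, but between 118% and 135% in the naive library. In single cells with at least 15 class II UMIs, an H2-Eb1 share under 5% was found in 221 of 771 infected and 0 of 891 naive B cell-like cells, which allows a naive share of up to 0.413%, and in 50 of 126 infected and 2 of 213 naive conventional dendritic cell 2-like cells. These values leave out alveolar macrophage-like cells, where H2-Eb1 fell from 43.8 to 9.22 CPM in male and from 122 to 18.6 in female cells. A lack in male cells alone would not account for that fall. Other genes differed by sex in some classes, such as H2-T23, from 89.4 to 17.3 CPM in male but from 67.7 to 64.9 in female alveolar macrophage-like cells. Among female cells H2-T23 fell from 408 to 160 in neutrophil-like and from 295 to 182 in conventional dendritic cell 2-like cells. In female T cell-like cells it went from 284 to 296. A difference between the mice of the pools thus stays open beyond H2-Eb1, and the H2-Eb1 change cannot be assigned to infection.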

How the results depend on the processing

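The alternatives on male and female cells, low-UMI, proliferating and interferon-stimulated clusters, cells holding markers of other types, tertiles, the limit of 10 Cxcl2 UMIs and a common doublet threshold were chosen after seeing the data. No paired analysis was possible because each group has 1 library. For the 16 results that answer comparisons, 139 of 196 alternatives kept the value within its counting interval, 56 moved it and 1 reversed it; for 74 other results the numbers were 709, 293 and 16 of 1018. In alveolar macrophage-like cells the Cxcl2 log2 ratio ran from 1.10 to 1.46 and the inflammatory median from 0.61 to 0.98, while the class II median ran from -0.98 to 0.39. The neutrophil-like share ran from 11.997% to 16.0% naive and from 36.7% to 43.4% infected. With doublets kept, Cxcl2 was 1.46, class II -0.46, alternative activation reversed to 0.0275 and the infected Cxcl2 split had an immediate-early median of 0.37. At the 5% mitochondrial limit the neutrophil-like shares were 16.0% and 43.4%, Cxcl2 1.31, the inflammatory median 0.92, class II -0.45, lipid handling reversed to -0.00703, and the immediate-early splits were 0.73 naive and 0.43 infected. At 1000 UMIs or more per cell the naive alveolar macrophage-like share was 17.0%, Cxcl2 1.44, the inflammatory median 0.93, class II -0.49, alternative activation 0.0310 and Scgb1a1 0.31 (both reversed), the Cxcl2-positive shares 82.2% and 95.4% and the naive immediate-early split 0.69. Under the marker gate (430 and 138 cells) Cxcl2 was 1.42, class II 0.39, complement 1.36 and lipid handling -0.0787 (all 3 reversed), the infected Cxcl2-positive share 95.7% and the naive inflammatory split 0.31. Scaling by the median ratio gave Cxcl2 1.45, class II -0.84, oxidative phosphorylation 0.0201 (reversed) and a neutrophil-like inflammatory median of 0.93. Weighting cells equally gave Cxcl2 1.10, class II -0.72, cell cycle 0.0866 and neutrophil granules -0.38 (both reversed) and a nonclassical inflammatory median of 0.85. Without a UMI minimum per gene the neutrophil-like inflammatory median was 0.55, and at 100 UMIs the naive inflammatory split was 0.38. Without thinning the infected inflammatory split was 1.57. At 4500 UMIs the Cxcl2-positive shares were 73.2% and 89.9% and the immediate-early splits 0.73 and 0.33. The Cxcl2-positive shares were 69.2% and 88.4% at 2 UMIs, 64.2% and 84.9% at 3, and 41.3% and 67.6% at 10, lower by construction. Tertiles gave immediate-early splits of 0.95 naive and 0.43 infected and a naive inflammatory split of 0.75. Without the low-UMI cluster the alveolar macrophage-like shares were 14.9% and 9.28%, without the proliferating cluster Cxcl2 was 1.26, and without the interferon-stimulated cluster the neutrophil-like shares were 11.997% and 36.7%. Without cells holding markers of another type (577 and 290 cells left) the inflammatory median was 0.98, class II -0.35, complement 0.62 and lipid handling -8.84e-05 (both reversed), the infected Cxcl2-positive share 95.2% and the infected immediate-early split 0.40. Male cells alone gave an alveolar macrophage inflammatory median of 0.92, class II -0.15, and reversed values of -0.10 for interferon-stimulated genes, 0.33 for complement, 0.0948 for alternative activation, -0.16 for lipid handling and -0.0412 for lysosome genes, with inflammatory medians of 0.53 in neutrophil-like and 0.30 in classical monocyte-like cells. The interferon-stimulated and complement medians of male cells rest on 7 and 4 measured members, against 12 and 7 in female cells. Female cells alone gave an inflammatory median of 0.96 in classical monocyte-like cells. Except where construction is named, the cause was not tested. The counting interval of the infected inflammatory split, with its 36 Cxcl2-negative cells, ran from 0.68 to 1.37, and that of the interferon-stimulated list from 0.79 to 1.38.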

Other observations

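No hypothesis is tested in this part, and the values were chosen after they were seen. Some transcripts moved the same way in all 12 compared classes, among 4310 genes measured in each. Ldha, which encodes lactate dehydrogenase A and marks a shift to lactate production, had a median log2 ratio of 0.50 over the classes, from 0.09 in the lowest to 1.01 in the highest. The linker histone gene Hist1h1e had a median of -1.02, and the mitochondrial leucyl-tRNA synthetase gene Lars2 of -0.68. The features Gm42418, AY036118 and AC149090.1 were lower as well, with medians of -0.54, -0.65 and -0.79. The class I-like gene H2-T23 (chromosome 17, 36029773 to 36032855), whose product engages inhibitory receptors of natural killer cells, had a median of -0.57. H2-T23 went from 89.4 to 17.3 CPM in male and from 67.7 to 64.9 in female alveolar macrophage-like cells. In neutrophil-like cells it fell in both sexes, from 320 to 87.2 in male and from 408 to 160 in female cells. The gene models Gm10260 and Gm11361 had medians of 1.71 and 1.44. In B cell-like cells Gm10260 stood at 8.13 CPM in naive male, 213 in naive female, 897 in infected male and 330.1 in infected female cells. The cause of these shifts was not tested.

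Cxcl2 UMIs were also found outside macrophages, monocytes and neutrophils. Group 2 innate lymphoid cell-like cells held 6088 naive and 8474 infected Cxcl2 CPM, and basophil or mast cell-like cells, compared in no list because of their small number, held 7444 in 28 naive and 6518 in 15 infected cells. Migratory dendritic cell-like cells held 247 in 24 naive and 2644 in 69 infected cells. The part of the Cxcl2 in these classes that came with neutrophil RNA was not measured. Interstitial macrophage-like cells held 23.5% of the naive and 6.06% of the infected library's Cxcl2 UMIs. GFP per 100 Cxcl2 UMIs lay between 35.1 and 61.1 over the 6 of the 12 compared classes with over 1000 Cxcl2 CPM in the naive library, and between 34.6 and 48.9 over the 8 in the infected library.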
